A study of Homo sapiens with 18 samples.

How the data were processed

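Small RNA of 6 groups of cultured human cells was sequenced, with 3 libraries per group that the labels call biological replicates. The data used here are the deposited table of raw counts for 18 libraries, 1 line per mature miRNA at each of its loci on GRCh38, with chromosome, start, end and strand. Per the file headers the same table also holds a log2 fold change, a p-value and an adjusted p-value for 5 comparisons. Per the submitters' processing notes reads were trimmed with cutadapt and differences were tested with DESeq2 on GRCh38, without versions. The aligner and the counting tool are not given in the sources used here. The authors' deposited log2 values and p-values were not used in any test. For reference, their deposited FDR is below 0.05 for 243 entries higher and 228 lower in TSCp against TSCn, 403 and 393 in primed against naive H9, 362 and 383 in TSCn against naive H9, 240 and 424 in TSCp against primed H9, and 62 and 97 in CT30 against bTS5.

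The table has 2883 entries with 2652 mature names, and 169 names have more than 1 locus (400 entries). Of 91 such names with at least 100 counts, 75 have copies whose lowest total is at least 95% of the highest, so reads that fit several loci appear to be counted at each. The 2193 entries with a count come to 1799 distinct miRNAs once copies and entries with equal counts are merged. No pair of libraries holds identical counts. All 18 per-sample columns were used and 0 were left out. No genome sequence or reads were at hand, so mouse and human reads could not be separated in the libraries grown on feeder cells.

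Counts were fitted in edgeR 4.0.16 under R 4.3.3. TMM scaling, the filterByExpr filter and a quasi-likelihood fit with 1 mean per group over all 18 libraries gave 8 contrasts: TSCn against TSCp, ESCn against ESCp, TSCn against ESCn, TSCp against ESCp, TSCn and TSCp each against the average of bTS5 and CT30, bTS5 against CT30, and the change along the naive route minus that along the primed route. An entry was called at a Benjamini-Hochberg adjusted p below 0.05, within each contrast. Adjusted p-values of single miRNAs are from this edgeR quasi-likelihood test. Standard errors were taken from the log2 fold change and its F statistic. CPM are after TMM scaling and given as mean ± SD of 3 libraries.

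Before the data were examined, 15 lists were fixed: C19MC, miR-371/miR-373, miR-302/miR-367, C14MC, let-7/miR-98, miR-17/miR-92 with its paralog clusters, miR-200/miR-141, HOX-cluster miRNAs, p53-responsive miRNAs, epithelial and trophoblast-expressed miRNAs, and markers of mesenchymal cells and fibroblasts, blood, endoderm and liver, muscle and neural tissue. MiR-34c, miR-192, miR-194 and miR-215 belong to 2 lists. Each list was tested against the other entries with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 15 lists, and again with the correlation estimated. Members were counted over all tested entries and adjusted over the list alone. Shares are a list's counts over all counts of a library, and they and the distances were compared by exact permutation of libraries, which with 3 against 3 gives no p below 0.1. Distances are Euclidean over log2 CPM of tested entries with a prior count of 2, from each library to the mean of the 6 reference libraries.

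Also fixed before the data were examined was the rule for which miRNAs are named. Among those called, with a mean of at least 100 CPM in the higher group and no overlap between sides, it takes the 8 with the largest rise and the 8 with the largest fall. It adds the 3 most abundant members of each list and the 5 most abundant miRNAs over all libraries, and for the difference between routes it has no overlap condition. Members named because a count was 5 or fewer, the C19MC members named by position and the miRNAs that set TSCp replicate 3 apart were chosen after their values were seen. Where every library of a group was at 0, a fold is a bound with 3 counts per library as floor, which is 0.189 to 0.552 CPM. Such entries (zeros) were set to their bound for a second list median. With 1 to 3 counts in a group the ratio is given with its counting interval. Host genes were read from GENCODE 29 on the same strand. Tests of clusters by position, with at least 3 tested entries on 1 strand and neighbouring starts at most 10 kb apart, used camera at the preset and at the estimated correlation and were chosen after the results of the lists were seen.

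The precision is set by depth and by the spread between replicates. Replicates of a group varied more than counting error allows (chi-square per degree of freedom 12.86 to 2906.58), with the ESCn libraries furthest apart, at 1198.3 to 2906.58. On simulated counts with the TSCn and TSCp depths and spread, 964 entries were tested. The fit called 24% of 96 entries changed 2-fold and 60.6% of 99 changed 4-fold, with 0 of the wrong sign, and 3.5% of calls were false.

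Alternatives were relative-log (RLE) scaling, library size alone, TMM without the 4 large clusters, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, only the compared groups, a block for the replicate number, a log2 fold change of at least 1, copies summed per name, and each library left out in turn. For distances they were a prior count of 0.5, the 10 CPM filter, Spearman correlation and each of C19MC and C14MC left out, and for shares the tested entries as denominator. One entry per distinct miRNA, and leaving out ESCn replicates 2 and 3 together, were added after the data had been seen. The labels pair no libraries across groups, and libraries with the same replicate number were no closer than others in most group pairs, so the block was used only as an alternative. Other splits of the libraries were refitted in the same way, 100 drawn at random for the difference between routes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.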

Results

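The series measured mature miRNAs in 6 groups of cultured human cells, each with 3 libraries labelled as biological replicates. The ESC groups were H9 embryonic stem cells, in the naive state on mouse feeder cells (ESCn) and in the primed state on a feeder-free matrix (ESCp). TSCn and TSCp were trophoblast stem cells made from naive and from primed H9 cells, the primed ones with BMP4. The blastocyst-derived line bTS5 and the first-trimester line CT30 served as the reference trophoblast stem cells. Library totals ran from 6203424 counts in ESCn replicate 1 to 13904185 in TSCp replicate 3, and 2193 of 2883 entries, each a mature miRNA at one locus, had a count in at least 1 library. After the low-count filter 1003 entries with 880 names were tested.

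The most abundant miRNA differed from group to group. In bTS5 it was miR-21-5p, a miRNA active in many growing and repairing tissues, with 149000 ± 5200 CPM (mean ± SD, n = 3). ESCp was led by miR-302a-5p of the pluripotency-linked miR-302/miR-367 cluster at 270000 ± 3800 CPM, and TSCp by miR-372-3p of the miR-371/miR-373 cluster at 191000 ± 16000 CPM. In TSCn and CT30 the highest was miR-30d-5p, known from epithelial and endocrine tissues, at 95600 ± 2300 and 134000 ± 12000 CPM. ESCn was divided, with miR-372-3p first in replicate 1 and miR-21-5p first in replicates 2 and 3.

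Large clusters made up much of several libraries. The primate-specific chromosome 19 cluster C19MC, a placental cluster, held 47.4 ± 0.33% of counts in TSCn, 28.5 ± 2.1% in bTS5, 27.5 ± 0.54% in CT30, 8.34 ± 2.3% in ESCn, 2.44 ± 0.058% in TSCp and 0.595 ± 0.012% in ESCp. The adjacent miR-371/miR-373 cluster, known from early embryos and germ cell tumours, held 31.8 ± 0.55% in TSCp, 17.4 ± 10% in ESCn, 15.5 ± 0.69% in CT30, 13.3 ± 1.8% in bTS5, 1.20 ± 0.025% in TSCn and 0.427 ± 0.041% in ESCp. MiR-302/miR-367 held 50.4 ± 0.77% in ESCp and 3.15 ± 1.6% in ESCn. The imprinted chromosome 14 cluster C14MC, transcribed from the maternal copy, held 3.45 ± 1.1% in ESCn, 0.259 ± 0.12% in bTS5 and 0.0564 ± 0.043% in CT30. The let-7/miR-98 family, which builds up as cells differentiate, held 18.7 ± 7.2% in ESCn and 0.0701% in ESCp. With 3 libraries a side the smallest exact permutation p for any share was 0.1.

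**Figure D1:**
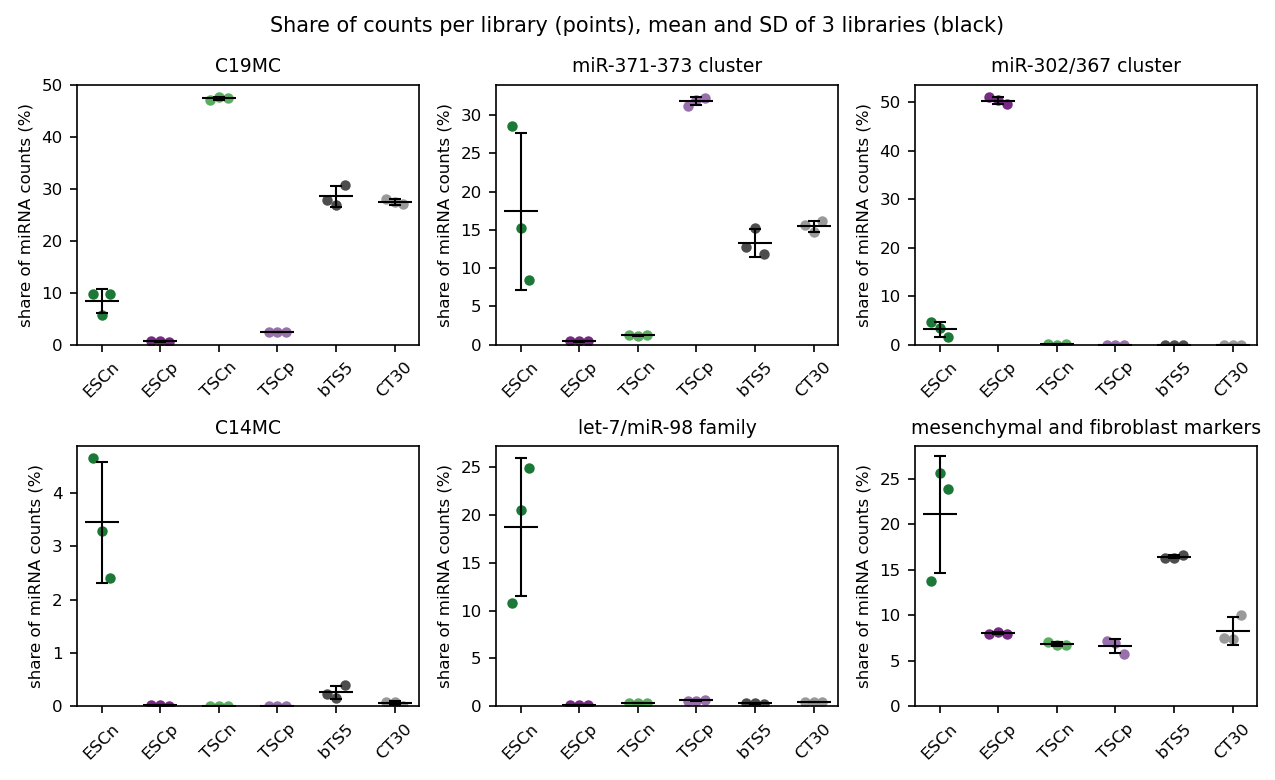
Share of each library's counts (vertical axis, %) held by 6 miRNA groups in the 6 cell groups (horizontal axis), 1 point per library, with black marks and bars for the mean ± SD of 3 libraries. C19MC reached 47.4 ± 0.33% in TSCn and 2.44 ± 0.058% in TSCp.

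Trophoblast stem cells from the naive and primed routes differed most at C19MC. In TSCn 82 of its 83 tested entries were higher than in TSCp and 1 was not past the threshold (miR-522-3p, log2 fold change 0.02), with a median of 7.43, or 172-fold (camera adjusted p = 4.52e-92, adjusted p = 0.000328 with an estimated correlation). MiR-512-3p, a placental C19MC member linked to trophoblast survival, rose 187-fold (7.54 ± 0.20, mean ± SE, n = 3 against 3, adjusted p = 1.6e-15, 48700 ± 2400 against 261 ± 15 CPM). MiR-516b-5p rose from 136 ± 27 to 28200 ± 1000 CPM and miR-515-5p, known to restrain human trophoblast fusion, from 9.30 ± 1.4 to 4590 ± 690 CPM (492-fold, 8.94 ± 0.29). The largest ratio was that of miR-515-3p (9.09 ± 0.40, 545-fold), ahead of miR-520f-5p (9.06 ± 0.43), miR-518e-3p (8.88 ± 0.34), miR-518c-5p (8.77 ± 0.40), miR-520f-3p (8.76 ± 0.38), miR-518a-3p (8.61 ± 0.40) and miR-498-3p (8.58 ± 0.37). MiR-516a-5p moved far less, 4.04-fold (2.01 ± 0.20, 25400 ± 580 against 6280 ± 1300 CPM). MiR-520f-5p had few counts in TSCp, and its log2 fold change became 9.80 without TSCp replicate 2.

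All 6 tested miR-371/miR-373 entries were lower in TSCn (median −4.61, camera adjusted p = 2.17e-06, adjusted p = 0.148 with an estimated correlation). MiR-372-3p, which shares its seed with the 3p strands of the miR-302 family and favours reprogramming, fell 23.1-fold (−4.53 ± 0.30, adjusted p = 3.7e-10, 8250 ± 230 against 191000 ± 16000 CPM). MiR-371a-5p fell 25.8-fold (−4.69 ± 0.30), miR-371a-3p 21.7-fold (−4.44 ± 0.31), and miR-373-3p, reported to promote cell migration, 33.8-fold (−5.08 ± 0.41). MiR-373-5p was at −5.0 ± 0.42. Of 11 p53-responsive entries 8 were lower and 3 not past the threshold (median −2.40, camera adjusted p = 0.00037, adjusted p = 0.0186 with an estimated correlation, −3.44 without TSCn replicate 1). MiR-34c-5p, of the miR-34 family that slows the cell cycle, fell 189-fold (−7.56 ± 0.43, adjusted p = 3.5e-11, 25.8 ± 1.8 against 4880 ± 2000 CPM) and miR-34a-5p fell 13.5-fold (−3.76 ± 0.27). Among miRNAs outside the large clusters, miR-486-5p, abundant in red blood cells, fell 38.7-fold (−5.28 ± 0.53), miR-574-5p 28.7-fold (−4.84 ± 0.32), and miR-148a-3p, known from liver and placenta, 2.52-fold (−1.33 ± 0.18).

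The miR-200/miR-141 family, which keeps the epithelial state by holding back ZEB1 and ZEB2, divided by locus: 5 of 9 entries were higher in TSCn, 1 lower and 3 not past (median 3.5, camera adjusted p = 0.0507). MiR-200b-3p on chromosome 1 rose 16.6-fold (4.06 ± 0.29), whereas miR-200c-3p on chromosome 12 fell 3.54-fold (−1.82 ± 0.19, 2340 ± 95 against 8300 ± 520 CPM) and miR-141-3p was at −0.15 ± 0.30. Of 28 entries of the growth-promoting miR-17/miR-92 group 12 were higher and 6 lower (median 0.81, or 0.06 with zeros at their bound, camera adjusted p = 0.635). MiR-92a-3p was at 0.83 ± 0.29 (a call lost in 7 settings) and miR-20a-5p at 0.87 ± 0.17. Of 36 mesenchymal entries 4 were higher and 4 lower (median 0.06, −0.07 to −0.10 with relative-log and library-size scaling, the test pointed down, camera adjusted p = 0.768). MiR-21-3p rose 5.11-fold (2.35 ± 0.20) with miR-21-5p at 0.20 ± 0.19, and miR-424-3p rose 8.15-fold (3.03 ± 0.79, 4.16 without TSCp replicate 3).

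Of 9 HOX-cluster entries 4 were lower in TSCn than in TSCp (median −1.20, camera adjusted p = 0.228), with miR-10a-5p, which lies among the HOXB genes and tunes HOX transcripts, down 7.42-fold (−2.89 ± 0.40) and miR-196a-5p at −1.22 ± 0.39, a call lost in 4 settings. Of 20 let-7/miR-98 entries 3 were lower, 2 when adjusted over the list alone (median −0.57, camera adjusted p = 0.228), let-7e-3p, let-7g-5p and let-7e-5p (−1.73 ± 0.41); let-7f-5p was at −0.87 ± 0.44, or 0.16 without TSCp replicate 3. Of 12 blood entries 5 were lower (median −0.50, camera adjusted p = 0.0507, adjusted p = 0.148 with an estimated correlation). Of 9 endoderm entries 3 were lower (median −0.42, camera adjusted p = 0.367), miR-375-3p (−0.99 ± 0.23) and both copies of miR-194-5p. Of 6 muscle entries 4 were lower (median −2.54, camera adjusted p = 0.171), copies of miR-1-3p (−2.52 ± 0.53) and miR-133a-3p (−2.56 ± 0.59). Of 19 epithelial and trophoblast entries 5 were higher and 4 lower (median −0.25, camera adjusted p = 0.394). MiR-205-5p, a keratinocyte and trophoblast miRNA, and miR-224-5p stayed close, at −0.25 ± 0.32 and 0.16 ± 0.32. The neural list had 2 higher (miR-132-5p and miR-219a-1-3p) and 2 lower of 27 (median 0.26, −0.50 without TSCn replicate 2, mean −0.02, test down, camera adjusted p = 0.503), 1 and 2 when adjusted over the list alone. MiR-128-3p was lower (−1.72 ± 0.21), and miR-9-5p, a regulator of neural progenitors, was at 0.36 ± 0.16. No C14MC entry of 74 and no miR-302/miR-367 entry of 9 passed the edgeR quasi-likelihood test at an adjusted p below 0.05 (medians 0 and 0.54, or 0 and 0.28 with zeros, 49 of 74 and 2 of 9 entries, at their bound, camera adjusted p = 0.768 and 0.9). At an unadjusted p below 0.05 they had 0 and 2, and by DESeq2 0 in both. MiR-127-3p was at 3.35 against 1.65 CPM. In all, 239 entries were higher and 203 lower in TSCn (203 and 183 names). Scaling choice moved all entries together by −0.165 to 0.163 log2 and turned the balance: 54.1% of calls were higher, against 47.4% with relative-log and 46.7% with library-size scaling.

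Naive and primed H9 cells lay furthest apart, with 443 entries higher and 314 lower in ESCn (381 and 287 names). ESCn grew on mouse feeder cells, and its mesenchymal share, mostly miR-21-5p, was 21.1 ± 6.4% against 8.0 ± 0.12% in ESCp. MiR-302/miR-367, the cluster most closely tied to primed pluripotency, was lower at all 9 entries (median −4.13, camera adjusted p = 2.01e-05, adjusted p = 0.215 with an estimated correlation). MiR-302a-5p fell 12.9-fold (−3.69 ± 0.31, n = 3 against 3, adjusted p = 6.9e-09, 20900 ± 10000 against 270000 ± 3800 CPM), miR-302b-3p 9.63-fold (−3.27 ± 0.26) and miR-302d-3p 29-fold (−4.86 ± 0.39). MiR-371/miR-373 moved the other way at all 6 entries (median 5.17, camera adjusted p = 0.00319, adjusted p = 0.299 with an estimated correlation). MiR-372-3p rose 52.7-fold (5.72 ± 0.32, 172000 ± 87000 against 3270 ± 380 CPM), miR-371a-5p 75.4-fold (6.24 ± 0.33) and miR-371a-3p 61.2-fold (5.93 ± 0.34). C19MC was higher at 79 of 83 entries and not past at 4 (median 3.06, camera adjusted p = 3.73e-17, adjusted p = 0.164 with an estimated correlation). MiR-516b-5p rose 60.3-fold (5.91 ± 0.22, 14700 ± 3600 against 243 ± 7.1 CPM), miR-1323 41.2-fold (5.36 ± 0.33) and miR-512-3p 11.6-fold (3.54 ± 0.17, 10300 ± 1300 against 885 ± 21 CPM).

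The miR-17/miR-92 group fell at 24 of 28 entries and rose at 2, miR-92a-1-5p and miR-25-5p (median −3.62, camera adjusted p = 8.94e-10, adjusted p = 0.164 with an estimated correlation). Its X-linked copies led: miR-20b-5p fell 1210-fold (−10.24 ± 0.37, adjusted p = 4.3e-13, 11.2 ± 3.5 against 13600 ± 630 CPM), miR-106a-5p 529-fold (−9.05 ± 0.37) and miR-363-3p 297-fold (−8.21 ± 0.51, 77.3 ± 48 against 22900 ± 980 CPM). MiR-20a-5p of the chromosome 13 copy fell 25.9-fold (−4.69 ± 0.19), and miR-92a-3p, which lies in both copies, 2.43-fold (−1.28 ± 0.29). The miR-200/miR-141 family again divided, with 4 of 9 entries higher and 5 lower (median −3.19, camera adjusted p = 0.202). MiR-200c-3p rose 7.05-fold (2.82 ± 0.19), and miR-200b-3p fell 58.6-fold (−5.87 ± 0.32, 44.7 ± 17 against 2620 ± 42 CPM), miR-200a-3p 88.8-fold (−6.47 ± 0.32) and miR-429 341-fold (−8.41 ± 0.48, −9.54 without ESCn replicate 2). MiR-135a-5p, studied in WNT signalling, fell 300-fold (−8.23 ± 0.55), miR-653-5p 170-fold (−7.41 ± 0.48, −8.23 without ESCn replicate 3) and miR-598-3p 119-fold (−6.89 ± 0.65). Of 27 neural entries 15 were lower and 7 higher (median −1.11, camera adjusted p = 0.0197, adjusted p = 0.25 with an estimated correlation), among them miR-9-5p (−1.11 ± 0.16) and miR-7-5p, abundant in brain and islets (2.56 ± 0.29).

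Several groups that mark differentiated cells were higher in ESCn together with the mesenchymal markers (21.1 ± 6.4% against 8.0 ± 0.12% of counts). All 20 let-7/miR-98 entries rose (median 8.86, 7.67 with zeros at their bound, camera adjusted p = 1.3e-07, adjusted p = 0.215 with an estimated correlation). Let-7i-5p rose 1900-fold (10.89 ± 0.55, 75600 ± 33000 against 39.8 ± 13 CPM), let-7f-5p 559-fold (9.13 ± 0.62), and let-7d-5p (10.93 ± 0.65), let-7c-5p (10.86 ± 0.52) and let-7a-5p (6.94 ± 0.37) were also higher. Of 36 mesenchymal entries 27 rose and 2 fell, miR-21-3p and miR-450b-5p (median 5.07, camera adjusted p = 1.3e-05, adjusted p = 0.299 with an estimated correlation, 5.77 without ESCp replicate 1). MiR-143-3p, a smooth muscle and fibroblast miRNA, rose 238-fold (7.90 ± 0.41, 24900 ± 11000 against 104 ± 15 CPM), miR-99a-5p (10.40 ± 0.45, 13300 ± 5200 against 9.82 ± 3.9 CPM) and miR-214-3p of the DNM3OS transcript (10.41 ± 0.60) were also higher, and miR-21-5p rose 2.13-fold (1.09 ± 0.19, lost in 3 settings). MiR-214-5p had 3 counts in ESCp, a ratio of 4440 (counting interval 1520 to 21600). All 9 HOX-cluster entries rose (median 8.22, camera adjusted p = 0.000152, adjusted p = 0.215 with an estimated correlation). MiR-10a-5p rose 298-fold (8.22 ± 0.51, 2180 ± 590 against 7.27 ± 4 CPM), miR-10b-5p by 206-fold (7.69 ± 0.31) and miR-196b-5p from 3 counts by a ratio of 5630 (counting interval 1930 to 27300).

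C14MC, silent in many human stem cell lines when its imprint is lost, was higher in ESCn at all 74 entries (median 7.78, 6.94 with 13 zeros at their bound, camera adjusted p = 5.72e-12, adjusted p = 0.299 with an estimated correlation). Its ESCn share did not follow the mesenchymal one. MiR-127-3p, which restrains the neighbouring RTL1 gene, rose 415-fold (8.70 ± 0.78, 12800 ± 2300 against 30.8 ± 11 CPM), miR-379-5p 251-fold (7.97 ± 0.73) and miR-381-3p 1350-fold (10.40 ± 0.90, 10300 ± 5000 against 7.58 ± 2.5 CPM). Of 11 p53-responsive entries 7 were higher (median 2.01, camera adjusted p = 0.168). Their share in ESCn replicates 1 to 3 was 0.457%, 0.892% and 0.675%, beside mesenchymal shares of 13.7%, 25.6% and 23.9%. MiR-34c-5p rose 31.3-fold (4.97 ± 0.38) and miR-34b-3p by 181-fold (7.50 ± 0.49). Among endoderm markers 4 of 9 were higher (median 0.88, camera adjusted p = 0.465). Liver-rich miR-122-5p rose 1280-fold (10.32 ± 0.80, 905 ± 790 against 0.693 ± 0.35 CPM, 9.31 without ESCn replicate 3). Blood markers had 4 higher and 3 lower of 12 (median 0.39, −0.10 with relative-log scaling, mean 0.90, test down, camera adjusted p = 0.723). Myeloid miR-223-5p was higher and miR-126-5p at −4.84 ± 0.36. Epithelial and trophoblast markers had 5 higher and 7 lower of 19 (median −0.23, mean 0.43, camera adjusted p = 0.643), and muscle markers 2 and 2 of 6 (median −1.0, −2.11 without ESCn replicate 3, mean 0.26, camera adjusted p = 0.643). MiR-206 was at 6.41 ± 0.64. MiR-148a-3p was at 65500 against 62000 CPM (0.08 ± 0.18). Relative-log scaling moved all entries of this comparison by −0.50 log2, library size by −0.398 and scaling without the large clusters by −0.252; no listed group with a camera adjusted p below 0.05 changed direction.

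Along the naive route, from ESCn to TSCn, pluripotency clusters fell and the placental C19MC rose. All 9 miR-302/miR-367 entries fell (median −8.16, camera adjusted p = 1.32e-05, adjusted p = 0.229 with an estimated correlation). MiR-302a-5p fell 359-fold to 58.2 ± 15 CPM (−8.49 ± 0.39, n = 3 against 3). MiR-302b-3p fell 460-fold (−8.85 ± 0.33) and miR-302a-3p by 285-fold (−8.16 ± 0.45). All 6 miR-371/miR-373 entries fell (median −3.24, −2.62 without ESCn replicate 1, camera adjusted p = 0.00668, adjusted p = 0.303 with an estimated correlation). MiR-372-3p fell 20.9-fold (−4.39 ± 0.30). MiR-371a-5p fell 13.5-fold (−3.75 ± 0.29) and miR-371a-3p by 16.6-fold (−4.05 ± 0.31). C19MC rose at 82 of 83 entries (median 3.16, 2.43 with zeros at their bound, camera adjusted p = 6.28e-30, adjusted p = 0.0407 with an estimated correlation). MiR-512-3p rose 4.72-fold (2.24 ± 0.16), miR-1323 3.09-fold (1.63 ± 0.28), miR-516b-5p 1.92-fold (0.94 ± 0.18), miR-515-3p 38.9-fold (5.28 ± 0.32), miR-520f-5p 34.5-fold (5.11 ± 0.34) and miR-518c-3p 28.4-fold (4.83 ± 0.24). MiR-483-3p and miR-483-5p, hosted by the fetal growth gene IGF2, rose 448-fold (8.81 ± 0.53, 624 ± 21 against 1.35 ± 1.2 CPM, 9.85 without ESCn replicate 3) and 477-fold (8.90 ± 0.57, 9.55 without ESCn replicate 3). MiR-934, within the trophoblast gene VGLL1, rose 54-fold (5.75 ± 0.56, 3170 ± 130 against 58.6 ± 46 CPM, 6.60 without ESCn replicate 3).

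Of 9 miR-200/miR-141 entries 8 were higher in TSCn than in ESCn (median 2.23, camera adjusted p = 0.00252, adjusted p = 0.229 with an estimated correlation). MiR-200b-3p rose 9.23-fold (3.21 ± 0.28) and miR-200a-3p by 33.9-fold (5.09 ± 0.31), while miR-200c-3p was at 0.32 ± 0.18. The chromosome 8 neighbours miR-30b-5p and miR-30d-5p rose 161-fold (7.33 ± 0.28, 11400 ± 230 against 70.7 ± 14 CPM) and 9.28-fold (3.21 ± 0.22), and miR-30d-3p rose 54.7-fold (5.77 ± 0.34). Of 19 epithelial and trophoblast entries 9 rose and 7 fell (median 1.08, camera adjusted p = 0.406). MiR-205-5p rose 14.9-fold (3.90 ± 0.36, 5410 ± 110 against 363 ± 270 CPM, 4.69 without ESCn replicate 1) and miR-224-5p 3.66-fold (1.87 ± 0.33, 2.56 without ESCn replicate 3). Of 28 miR-17/miR-92 entries 15 rose and 8 fell (median 0.97, camera adjusted p = 0.0123, adjusted p = 0.371 with an estimated correlation). MiR-20a-5p rose 25.4-fold (4.67 ± 0.19, 14500 ± 1300 against 572 ± 38 CPM), miR-92a-3p 3.55-fold (1.83 ± 0.30), and miR-25-3p fell 2.50-fold (−1.32 ± 0.16). Neural entries were 7 higher and 17 lower of 27 (median −1.49, camera adjusted p = 0.847). MiR-9-5p rose 14.5-fold (3.86 ± 0.18, 12000 ± 120 against 828 ± 210 CPM), and miR-7-5p fell 4.58-fold (−2.19 ± 0.29) and miR-128-3p 4.79-fold (−2.26 ± 0.21).

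The groups that were high beside the mesenchymal markers in ESCn (share 21.1 ± 6.4%, 6.82% in TSCn) all fell. So did C14MC, whose share was highest in the ESCn library with the lowest mesenchymal share. C14MC fell at 74 of 74 entries (median −10.39, −8.21 with 37 zeros at their bound, camera adjusted p = 3.13e-19, adjusted p = 0.225 with an estimated correlation). MiR-127-3p fell 3810-fold (−11.90 ± 0.88), miR-379-5p 3870-fold (−11.92 ± 0.88), miR-381-3p 4750-fold (−12.21 ± 0.97), miR-409-3p 5340-fold (−12.38 ± 0.92), miR-485-3p at least 543-fold and miR-329-3p at least 388-fold. MiR-134-5p, a regulator of dendrite growth, fell 7450-fold (−12.86 ± 0.98, −14.35 without TSCn replicate 1), and miR-323a-3p and miR-654-5p, with 1 count each in TSCn, fell by ratios of 14800 (counting interval 2650 to 584000) and 10800 (1930 to 426000). Let-7/miR-98 fell at 19 of 20 entries (median −7.06, −6.32 with zeros at their bound, camera adjusted p = 3.21e-07, adjusted p = 0.225 with an estimated correlation). Let-7i-5p fell 3290-fold (−11.68 ± 0.57), let-7f-5p 136-fold (−7.09 ± 0.57) and let-7a-5p 22-fold (−4.46 ± 0.33). HOX-cluster entries fell at 8 of 9 (median −6.00, camera adjusted p = 0.000197, adjusted p = 0.225 with an estimated correlation). MiR-10b-5p fell 781-fold (−9.61 ± 0.34), miR-10a-5p 91.6-fold (−6.52 ± 0.47) and miR-196b-5p 603-fold (−9.24 ± 0.70). Mesenchymal entries fell at 27 of 36 and rose at 7 (median −5.08, camera adjusted p = 4.75e-06, adjusted p = 0.256 with an estimated correlation). MiR-143-3p fell 250-fold (−7.97 ± 0.41), miR-99a-5p 1090-fold (−10.09 ± 0.44), miR-21-5p 2.48-fold (−1.31 ± 0.19), and miR-214-3p, with 2 counts in TSCn, by a ratio of 15900 (counting interval 4400 to 131000).

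The p53-responsive list, with its share in ESCn in the same order over libraries as the mesenchymal share (21.1 ± 6.4%, 6.82% in TSCn), fell at 7 of 11 entries (median −2.25, −1.20 without ESCn replicate 3, camera adjusted p = 0.0123, adjusted p = 0.225 with an estimated correlation). MiR-34c-5p fell 254-fold (−7.99 ± 0.43) and miR-34b-3p 1290-fold (−10.33 ± 0.57, −10.97 without TSCn replicate 3). Blood markers fell at 8 of 12 entries and rose at 2, miR-144-5p and miR-126-5p (median −3.98, −3.18 without ESCn replicate 1, camera adjusted p = 0.138), including inflammation-linked miR-155-5p by a ratio of 1150 (counting interval 394 to 5580) and miR-486-5p by 16.5-fold (−4.05 ± 0.50, −3.18 without ESCn replicate 1). Endothelial miR-126-3p was at −0.42 ± 0.18, a call lost in 11 settings, and 0.048 with no filter. Endoderm markers were 3 higher and 3 lower of 9 (median −0.60, mean 0.69, test up, camera adjusted p = 0.406). MiR-122-5p fell 608-fold (−9.25 ± 0.76, −8.23 without ESCn replicate 3). Muscle markers had 2 of 6 lower (median −0.68, 0.43 without ESCn replicate 3, camera adjusted p = 0.406), miR-206 by a ratio of 1070 (counting interval 297 to 8850) and miR-499a-5p 4.31-fold (−2.11 ± 0.49). The comparison had 333 entries higher and 388 lower (301 and 340 names), and scaling moved all entries by 0.059 to 0.37 log2. The balance turned, with 46.2% of calls higher, against 52% with library-size scaling and 51% with scaling without the large clusters.

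In the primed route miR-302/miR-367 was lost and miR-371/miR-373 gained. All 9 miR-302/miR-367 entries were lower in TSCp than in ESCp (median −12.46, −12.42 with zeros at their bound, camera adjusted p = 4.92e-13, adjusted p = 0.0931 with an estimated correlation). MiR-302a-5p fell 7140-fold (−12.80 ± 0.45, n = 3 against 3, adjusted p = 2.8e-13, 37.8 ± 5.2 against 270000 ± 3800 CPM), miR-302b-3p 6480-fold (−12.66 ± 0.38), miR-302a-3p 5630-fold (−12.46 ± 0.52), miR-302d-3p 5500-fold (−12.42 ± 0.54) and miR-302c-3p 5130-fold (−12.33 ± 0.58). MiR-367-3p, with 1 count in TSCp, fell by a ratio of 10400 (counting interval 1870 to 412000), and miR-302e, which lies on chromosome 11 outside the cluster, fell at least 495-fold. All 6 miR-371/miR-373 entries rose (median 6.24, camera adjusted p = 8.77e-08, adjusted p = 0.0931 with an estimated correlation). MiR-371a-5p rose 144-fold (7.17 ± 0.34, 73400 ± 6800 against 509 ± 47 CPM), miR-372-3p 58.3-fold (5.87 ± 0.32, 191000 ± 16000 against 3270 ± 380 CPM) and miR-373-3p 31.7-fold (4.99 ± 0.41), and miR-373-5p (6.53 ± 0.45), miR-371a-3p (6.33 ± 0.34) and miR-372-5p (6.15 ± 0.41) were also higher. MiR-934 rose 626-fold (9.29 ± 0.67, 1340 ± 600 against 2.09 ± 1.6 CPM, 10.13 without ESCp replicate 2), miR-483-3p 395-fold (8.62 ± 0.52, 651 ± 44 against 1.62 ± 0.82 CPM) and miR-675-5p, processed from the imprinted placental RNA H19, 351-fold (8.46 ± 0.91, 9.13 without ESCp replicate 2); miR-483-5p rose 405-fold (8.66 ± 0.53, 9.55 without that replicate). MiR-30d-5p rose 23.7-fold (4.56 ± 0.24, 136000 ± 14000 against 5740 ± 150 CPM).

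C19MC divided along the primed route: 20 of 83 entries rose, 54 fell and 9 were not past (median −1.30, camera adjusted p = 0.437). MiR-516a-5p rose 64.8-fold (6.02 ± 0.24, 6280 ± 1300 against 97 ± 3.6 CPM), miR-522-3p 39.8-fold (5.32 ± 0.23, 1880 ± 230 CPM in TSCp) and miR-1283 19.6-fold (4.29 ± 0.18). Of 23 entries in the final 13.7 kb, next to miR-371a, or with counts like one there, 19 rose. Of the other 60, 54 fell and 1, a miR-518a-5p copy, rose. Like counts are not independent, and the segment was set after values were seen. C14MC had 36 of 74 entries lower, 32 when adjusted over the list alone (median −3.53, −0.81 with 46 zeros at their bound, camera adjusted p = 0.0824). MiR-127-3p fell 18.6-fold (−4.22 ± 0.68), miR-379-5p 39.7-fold (−5.31 ± 0.75) and miR-370-3p 64.3-fold (−6.01 ± 0.88).

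**Figure D2:**
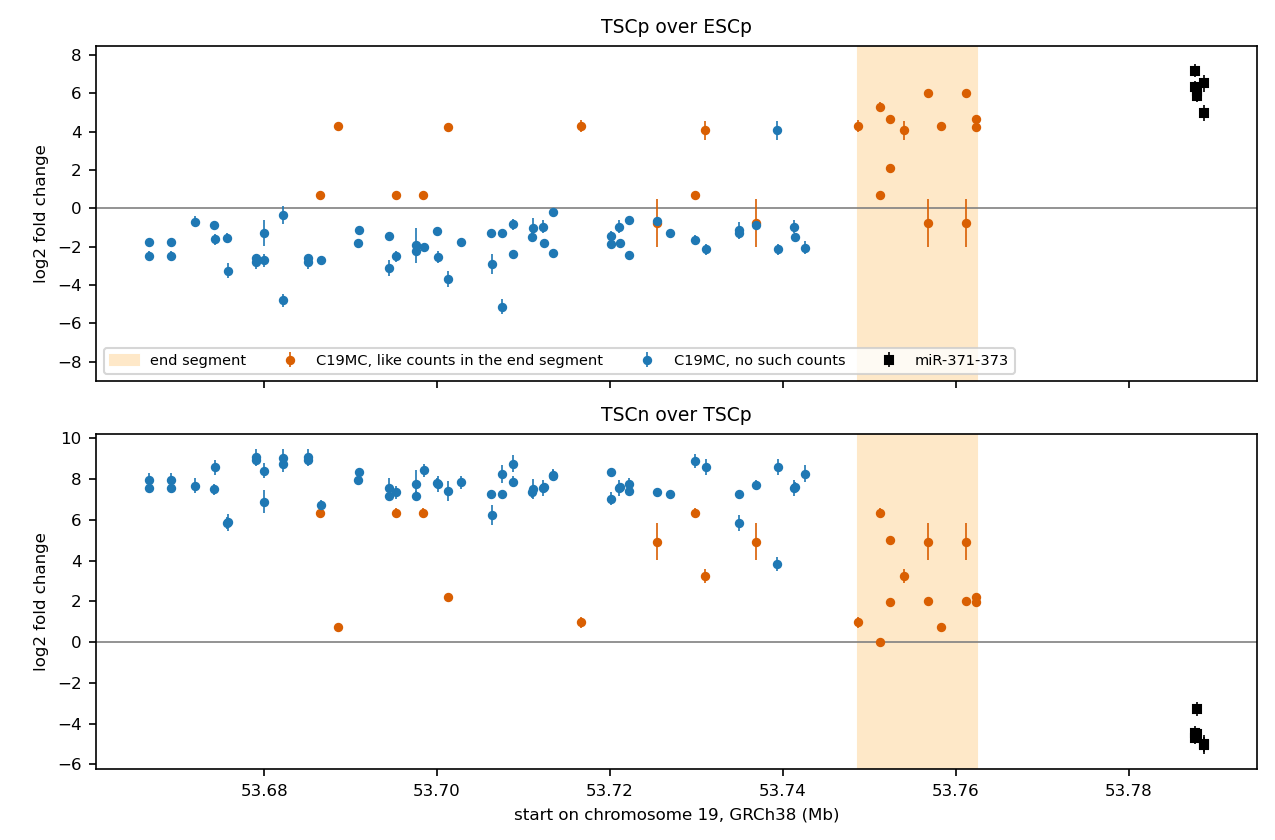
Log2 fold change ± SE of C19MC and miR-371/miR-373 entries (vertical axis) by start on chromosome 19 in Mb (horizontal axis), for TSCp over ESCp and for TSCn over TSCp, n = 3 libraries per group. The shaded end segment starts at 53748689; orange entries have counts like an entry in it, blue entries do not and black squares are miR-371/miR-373.

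The epithelial miR-200 loci parted in the primed route as well, with 4 of 9 entries higher and 5 lower (median −5.69, camera adjusted p = 0.437). MiR-200c-3p rose 31.1-fold (4.96 ± 0.21, 8300 ± 520 against 267 ± 13 CPM), miR-200b-3p fell 106-fold (−6.72 ± 0.33) and miR-200a-3p 107-fold (−6.74 ± 0.32). The miR-17/miR-92 group fell at 22 of 28 entries and rose at 2, miR-92a-1-5p and miR-25-5p (median −1.35, camera adjusted p = 3.63e-06, adjusted p = 0.125 with an estimated correlation). MiR-363-3p fell 5160-fold (−12.33 ± 0.60, 4.42 ± 0.72 against 22900 ± 980 CPM), miR-20a-5p 1.86-fold (−0.90 ± 0.17), with miR-92a-3p at −0.28 ± 0.29. Of 20 let-7/miR-98 entries 13 rose (median 2.66, 1.83 without TSCp replicate 3, camera adjusted p = 0.00113, adjusted p = 0.407 with an estimated correlation). Let-7a-5p rose 8.27-fold (3.05 ± 0.31), let-7f-5p 7.50-fold (2.91 ± 0.47, 1.83 without that replicate) and let-7g-5p 5.76-fold (2.53 ± 0.48, 1.33 without it). Of 9 HOX-cluster entries 7 rose and 1 fell (median 4.59, 4.18 with zeros at their bound, camera adjusted p = 0.0249, adjusted p = 0.407 with an estimated correlation). MiR-10a-5p rose 24.1-fold (4.59 ± 0.44, 5.2 without ESCp replicate 2), miR-196a-5p from 3 counts by a ratio of 217 (counting interval 74.4 to 1050), and miR-10b-5p fell 5.12-fold (−2.36 ± 0.26).

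Among endoderm markers 5 of 9 rose (median 1.41, camera adjusted p = 0.00113, adjusted p = 0.0931 with an estimated correlation). Islet and gut miR-375-3p rose 70.2-fold (6.13 ± 0.28). The p53-responsive list rose at 7 of 11 entries (median 1.41, camera adjusted p = 0.018, adjusted p = 0.0931 with an estimated correlation), miR-34c-5p 23.3-fold (4.54 ± 0.37) and miR-34a-5p 2.26-fold (1.17 ± 0.24). Of 19 epithelial and trophoblast entries 9 rose and 5 fell, 9 and 6 adjusted over the list alone (median 1.24, camera adjusted p = 0.103). MiR-205-5p rose 9.23-fold (3.21 ± 0.35) and miR-221-3p, an inhibitor of the cell-cycle brake p27, fell 4.13-fold (−2.05 ± 0.25). Neural entries were 12 higher and 8 lower of 27 (median 0.61, mean −2.11, test down, camera adjusted p = 0.887). MiR-9-5p rose 5.23-fold (2.39 ± 0.17) and miR-7-5p 1.94-fold (0.96 ± 0.28, lost in 2 settings). Mesenchymal entries were 8 higher and 15 lower of 36 (median −0.31, test up, camera adjusted p = 0.901). MiR-100-5p was at −2.78 ± 0.36 and miR-21-5p at −0.42 ± 0.19. Blood entries were 4 higher and 5 lower of 12 (median −0.22, −0.95 without TSCp replicate 3, camera adjusted p = 0.977). MiR-155-5p fell 56.2-fold (−5.81 ± 0.59) and miR-486-5p rose 3.13-fold (1.64 ± 0.45). Muscle entries were 2 lower of 6, miR-206 and miR-499a-5p, the latter lost in 10 settings, 1 when adjusted over the list alone (median 0.11, −0.18 with relative-log scaling, mean −0.33, camera adjusted p = 0.901). In total 633 entries were called, 266 of them higher (223 names) and the rest lower (332 names), with scaling shifts of −0.295 to 0.136 log2.

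Routes were compared as the change from ESCn to TSCn minus that from ESCp to TSCp. MiR-371/miR-373 stood apart at all 6 entries (median −9.71, camera adjusted p = 9.39e-07, adjusted p = 0.0848 with an estimated correlation). MiR-372-3p was at −10.25 ± 0.43 and miR-371a-5p at −10.93 ± 0.45. C19MC was higher in the naive route at 68 of 83 entries and lower at 5, the copies of miR-1283 and miR-516a-5p and miR-522-3p (median 4.03, camera adjusted p = 5.8e-18, adjusted p = 0.0848 with an estimated correlation), miR-512-3p at 4.00 ± 0.22 and miR-515-3p at 8.08 ± 0.48. So were 20 of 28 miR-17/miR-92 entries, with 1 lower, miR-25-5p (median 3.76, 3.39 with zeros at their bound, camera adjusted p = 8.85e-07, adjusted p = 0.0848 with an estimated correlation), miR-20b-5p at 11.31 ± 0.44. The chromosome 1 miR-200 miRNAs had the largest positive values, miR-429 11.91 ± 0.61 (13.03 without ESCn replicate 2) and miR-200a-3p 11.82 ± 0.44, and miR-200c-3p a negative one of −4.64 ± 0.27, with 5 of 9 family entries higher and 4 lower (median 7.81, camera adjusted p = 0.12). Of 11 p53-responsive entries, which were high beside the mesenchymal share in ESCn (21.1 ± 6.4%), 7 were lower in the naive route, 8 adjusted over the list alone (median −3.67, −2.61 without ESCn replicate 3, camera adjusted p = 0.000428, adjusted p = 0.0848 with an estimated correlation), led by miR-34b-3p at −14.72 ± 0.71 (−15.36 without TSCn replicate 3) and miR-34c-5p at −12.53 ± 0.57. MiR-302/miR-367 fell less in the naive route at 7 of 9 entries (median 4.31, camera adjusted p = 0.00308, adjusted p = 0.336 with an estimated correlation). Both it and miR-17/miR-92 started lower in ESCn.

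Groups high in ESCn beside mesenchymal markers (share 21.1 ± 6.4%), and separately C14MC, gave large negative route differences. The let-7/miR-98 family was lower in the naive route at 19 of 20 entries (median −9.76, −8.92 without TSCp replicate 3, −9.39 with zeros at their bound, camera adjusted p = 4.21e-10, adjusted p = 0.0848 with an estimated correlation) and HOX-cluster miRNAs at 9 of 9 (median −10.63, camera adjusted p = 5.92e-06, adjusted p = 0.0848 with an estimated correlation). Mesenchymal markers were lower at 26 of 36 entries with 3 higher, miR-21-3p, miR-424-5p and miR-450b-5p (median −6.21, camera adjusted p = 1.54e-07, adjusted p = 0.217 with an estimated correlation). C14MC was lower at 18 of 74, 14 adjusted over the list alone (median −7.10, −6.59 with 49 zeros at their bound, camera adjusted p = 0.0491, adjusted p = 0.735 with an estimated correlation). Examples were let-7i-5p at −11.57 ± 0.64 (−10.90 without TSCp replicate 3), miR-10a-5p at −11.11 ± 0.64 (−11.74 without ESCp replicate 2), miR-143-3p at −7.74 ± 0.48 and miR-127-3p at −7.68 ± 0.95. MiR-486-5p was at −5.69 ± 0.67 (−4.82 without ESCn replicate 1) and miR-206 at −6.93 ± 1.74, a call lost without TSCp replicate 3 (−3.86). Together 306 entries were higher and 295 lower in the naive route (270 and 246 names), with scaling shifts of 0.235 to 0.415 log2. Of all tested entries 105 rose in both routes (88.3 expected from the separate counts, Fisher p = 0.0123), among them miR-483-3p, miR-934 and miR-30d-5p, 153 fell in both (142 expected, p = 0.139), as miR-302a-5p did, and 222 went opposite ways, as miR-372-3p did.

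**Figure D3:**
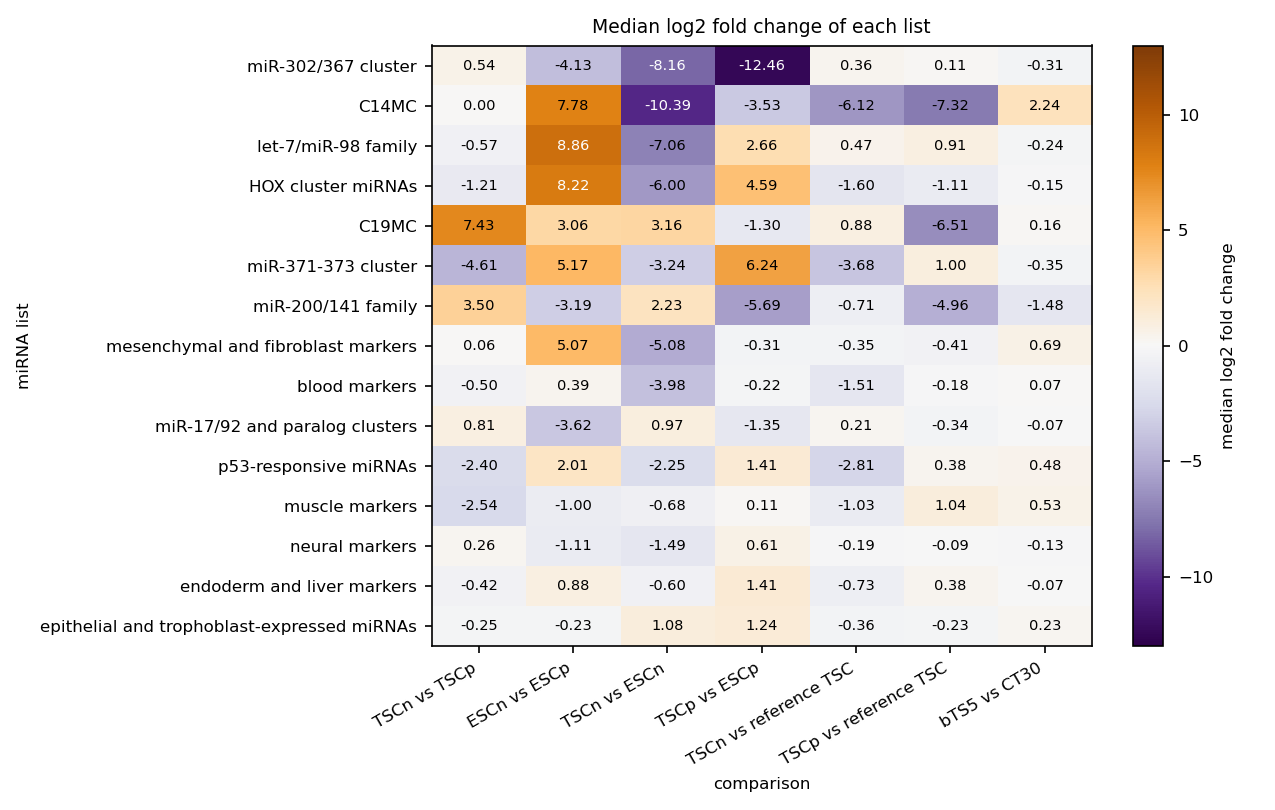
Median log2 fold change of 15 miRNA lists (vertical axis) in 7 comparisons (horizontal axis), printed in each cell and coloured by value, n = 3 libraries per group and 6 for the reference. C19MC had 7.43 in TSCn against TSCp and −6.51 in TSCp against the reference.

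Against the reference lines bTS5 and CT30 together, TSCn was higher at C19MC and lower at C14MC, miR-371/miR-373 and the miR-34 family. C19MC had 70 of 83 entries higher and 3 lower, miR-522-3p and both copies of miR-1283 (74 and 3 when adjusted over the list alone, median 0.88, camera adjusted p = 7.06e-23, adjusted p = 0.0373 with an estimated correlation). MiR-512-3p rose 2.00-fold (1.00 ± 0.13, n = 3 against 6, adjusted p = 1.1e-05, 48700 ± 2400 against 23700 ± 2100 in bTS5 and 25000 ± 5000 in CT30). MiR-516b-5p rose 1.53-fold (0.61 ± 0.15) and miR-520f-5p 9.0-fold (3.17 ± 0.24, 193 ± 5.6 against 9.83 ± 1.3 and 46.4 ± 6.1 CPM). MiR-520f-3p was at 2.77 ± 0.23, miR-526b-3p at 1.80 ± 0.28, miR-520b-3p at 1.76 ± 0.29 and miR-1323 at 0.42 ± 0.24. C14MC had 65 of 74 entries lower, 69 adjusted over the list alone (median −6.12, −4.42 with 37 zeros at their bound, camera adjusted p = 6.13e-20, adjusted p = 0.214 with an estimated correlation). MiR-127-3p fell 121-fold (−6.92 ± 0.72, 3.35 ± 0.45 against 782 ± 340 and 210 ± 160 CPM), miR-409-3p 142-fold (−7.15 ± 0.78), miR-379-5p 66-fold (−6.05 ± 0.70), miR-370-3p 60.9-fold (−5.93 ± 0.77) and miR-381-3p 59.1-fold (−5.88 ± 0.75). All 6 miR-371/miR-373 entries were lower (median −3.68, camera adjusted p = 4.57e-10, adjusted p = 0.0373 with an estimated correlation). MiR-372-3p fell 11.5-fold (−3.52 ± 0.27, 8250 ± 230 against 84200 ± 12000 and 107000 ± 1500 CPM), miR-371a-5p by 13-fold (−3.70 ± 0.28) and miR-373-3p by 15.5-fold (−3.95 ± 0.37). The p53-responsive miRNAs fell at 8 of 11 entries (median −2.81, −3.85 without TSCn replicate 1, camera adjusted p = 1.32e-06, adjusted p = 0.0102 with an estimated correlation), miR-34c-5p 55.5-fold (−5.79 ± 0.38, 25.8 ± 1.8 against 1690 ± 160 and 1220 ± 91 CPM) and miR-34a-5p 16.5-fold (−4.04 ± 0.26).

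Blood entries were lower in TSCn at 8 of 12 (median −1.51, −1.43 with zeros at their bound, camera adjusted p = 0.00232, adjusted p = 0.0373 with an estimated correlation) and HOX-cluster entries at 5 of 9 (median −1.60, −2.24 without TSCn replicate 2, camera adjusted p = 0.00214, adjusted p = 0.214 with an estimated correlation). MiR-486-5p fell 26.2-fold (−4.71 ± 0.49), miR-126-3p 1.57-fold (−0.65 ± 0.16), miR-10a-5p 22.6-fold (−4.50 ± 0.41) and miR-196a-5p 5.28-fold (−2.40 ± 0.37). Of 9 miR-200/miR-141 entries 5 were lower (median −0.71, camera adjusted p = 0.148), among them miR-200b-3p (−1.24 ± 0.24) and miR-200c-3p (−1.12 ± 0.17). Epithelial and trophoblast entries had 5 higher and 9 lower of 19 (median −0.36, camera adjusted p = 0.225), miR-205-5p at −0.94 ± 0.29 and miR-203a-3p at 0.01 ± 0.27. Mesenchymal entries had 3 higher and 10 lower of 36 (median −0.35, camera adjusted p = 0.225). MiR-21-5p fell 1.72-fold (−0.78 ± 0.17) and miR-22-3p 2.02-fold (−1.01 ± 0.23). Of 28 miR-17/miR-92 entries 7 were higher (median 0.21, camera adjusted p = 0.112), among them miR-92a-3p (0.81 ± 0.24) and miR-20a-5p (0.50 ± 0.14), and 1 of 20 let-7/miR-98 entries, let-7b-3p, 0 when adjusted over the list alone (median 0.46, camera adjusted p = 0.148). MiR-625-3p rose 4.18-fold (2.06 ± 0.18), miR-27a-5p 3.5-fold (1.81 ± 0.32) and miR-934 3.10-fold (1.63 ± 0.38), while miR-30d-5p was at 0.04 ± 0.18. Endoderm entries had 3 of 9 lower (miR-215-5p, miR-194-5p and miR-375-3p, the last lost in 10 settings, median −0.73, camera adjusted p = 0.433) and muscle 2 of 6 (copies of miR-133a-3p, lost in 8, median −1.03, camera adjusted p = 0.433). Neural entries had 1 higher (miR-219a-1-3p) and 3 lower of 27, 1 and 0 when adjusted over the list alone (median −0.19, camera adjusted p = 0.918), and miR-302/miR-367 0 of 9 by edgeR quasi-likelihood (2 at an unadjusted p below 0.05, 0 by DESeq2, median 0.36, camera adjusted p = 0.373). In all 184 entries were higher and 234 lower (162 and 218 names), and scaling moved all entries by −0.014 to 0.121 log2. The balance turned, with 44% of calls higher, against 50.4% with relative-log scaling and 51.1% with scaling without the large clusters.

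TSCp lacked most of the reference C19MC signal. C19MC had 79 of 83 entries lower (median −6.51, camera adjusted p = 7.46e-84, adjusted p = 0.000655 with an estimated correlation). MiR-512-3p fell 93.2-fold (−6.54 ± 0.19, n = 3 against 6, adjusted p = 5.2e-15), miR-1323 154-fold (−7.27 ± 0.36), miR-515-5p 260-fold (−8.02 ± 0.27), miR-518a-3p 210-fold (−7.72 ± 0.37), miR-498-3p 202-fold (−7.66 ± 0.35), miR-518e-3p 200-fold (−7.65 ± 0.32) and miR-523-3p 178-fold (−7.47 ± 0.30). MiR-516a-5p fell only 2.66-fold (−1.41 ± 0.18, 6280 ± 1300 against 16500 ± 2100 in bTS5 and 16900 ± 3700 in CT30). C14MC had 68 of 74 entries lower, 69 adjusted over the list alone (median −7.32, −4.04 with 44 zeros at their bound, camera adjusted p = 2.08e-07, adjusted p = 0.622 with an estimated correlation). MiR-409-3p fell 498-fold (−8.96 ± 0.88), miR-127-3p 245-fold (−7.94 ± 0.76) and miR-370-3p 225-fold (−7.81 ± 0.88). Of 6 miR-371/miR-373 entries 5 were higher (median 1.00, camera adjusted p = 0.0595). MiR-372-3p rose 2.01-fold (1.01 ± 0.22) and miR-373-3p by 2.18-fold (1.13 ± 0.29). MiR-200b-3p and miR-200a-3p fell 39.2-fold (−5.29 ± 0.30) and 55.4-fold (−5.79 ± 0.30) and miR-200c-3p rose 1.62-fold (0.70 ± 0.15), with 5 of 9 family entries lower and 1 higher (median −4.96, camera adjusted p = 0.0177, adjusted p = 0.622 with an estimated correlation).

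Of 20 let-7/miR-98 entries 9 were higher in TSCp (median 0.91, 0.87 with zeros at their bound, camera adjusted p = 0.00887, adjusted p = 0.622 with an estimated correlation). Let-7e-5p rose 5.82-fold (2.54 ± 0.34), let-7g-5p 5.44-fold (2.44 ± 0.38, 1.38 without TSCp replicate 3) and let-7f-5p 3.43-fold (1.78 ± 0.36, 0.82 without that replicate). MiR-941, a human-specific miRNA in an intron of DNAJC5 with 5 copies, rose 8.28-fold (3.05 ± 0.24, 694 ± 270 against 117 ± 18 and 60.2 ± 18 CPM), miR-421 5.06-fold (2.34 ± 0.23), miR-99b-3p 3.63-fold (1.86 ± 0.19) and miR-744-5p 3.22-fold (1.69 ± 0.24). Of 11 p53-responsive entries 4, miR-34b and miR-34c strands, were higher (median 0.38, −0.24 without TSCp replicate 3, camera adjusted p = 0.204). MiR-34c-5p rose 3.40-fold (1.77 ± 0.27) with miR-34a-5p at −0.28 ± 0.21. Of 9 HOX-cluster entries 6 were lower (median −1.11, camera adjusted p = 0.548), miR-10a-5p 3.04-fold (−1.61 ± 0.35), and 12 of 36 mesenchymal entries, with 1 higher, miR-450b-5p (median −0.41, camera adjusted p = 0.637), miR-21-5p 1.98-fold (−0.98 ± 0.17). The miR-17/miR-92 group had 5 higher and 10 lower of 28 (median −0.34, 0 with zeros at their bound, test up, camera adjusted p = 0.617), miR-20a-5p at −0.37 ± 0.15, a call lost in 16 settings. Epithelial and trophoblast entries had 3 higher and 5 lower of 19, 3 and 3 adjusted over the list alone (median −0.23, 0.02 with relative-log scaling, test up, camera adjusted p = 0.617). Muscle entries had 2 of 6 higher, 4 adjusted over the list alone (median 1.04, camera adjusted p = 0.204), miR-1-3p 3.06-fold (1.61 ± 0.41). Neural entries had 2 higher and 2 lower of 27, miR-132-5p and miR-219a-2-3p, 2 and 1 adjusted over the list alone (median −0.09, 0.15 with relative-log scaling, test up, camera adjusted p = 0.456), miR-128-3p 2.23-fold up (1.16 ± 0.17).

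Blood markers had 2 of 12 lower in TSCp than in the reference, miR-451a and miR-144-5p (median −0.18, −0.12 with zeros at their bound and 0.07 with relative-log scaling, test up, camera adjusted p = 0.639). Endoderm markers had 1 higher and 1 lower of 9, miR-483-3p and miR-122-5p, 0 when adjusted over the list alone (median 0.38, −0.48 without TSCp replicate 3, mean −0.06, camera adjusted p = 0.553). The miR-302/miR-367 cluster had 0 of 9 by edgeR quasi-likelihood, at an unadjusted p below 0.05 and by DESeq2 (median 0.11, camera adjusted p = 0.614). MiR-148a-3p rose 1.82-fold (0.87 ± 0.15), miR-30d-5p 1.46-fold (0.54 ± 0.17) and miR-483-3p 1.74-fold (0.80 ± 0.30, lost in 5 settings), and miR-205-5p was at −0.69 ± 0.29. In total 181 entries were higher and 315 lower (158 and 278 names), so 36.5% of calls were higher, against 47.6% with relative-log scaling, which moved all entries by 0.251 log2 (other scalings −0.041 and 0.151). TSCp replicate 3 stood apart from replicates 1 and 2. In it let-7g-5p was at 514.39 CPM against 104.41 and 106.73, miR-192-5p at 1781.55 against 416.80 and 411.99, miR-34c-5p at 2558.89 against 6089.35 and 5988.97, miR-10a-5p at 73.59 against 250.85 and 204.92, and miR-941 at 387.86 against 875.14 and 819.97. Without it miR-192-5p was lower than in the reference (−1.18, −0.25 with it) and miR-424-3p too (−2.42, −1.36 with it).

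The reference lines themselves differed at C14MC and the chromosome 1 miR-200 miRNAs. In bTS5 34 of 74 C14MC entries were higher than in CT30, 66 adjusted over the list alone (median 2.24, 1.72 without CT30 replicate 3, 2.21 with zeros at their bound, camera adjusted p = 2.27e-21, adjusted p = 0.336 with an estimated correlation). In CT30 the C14MC share was 0.0847%, 0.078% and 0.0064% in replicates 1 to 3. MiR-370-3p rose 5.35-fold (2.42 ± 0.62, n = 3 against 3, adjusted p = 0.021), miR-381-3p 5.03-fold (2.33 ± 0.63), miR-379-5p 4.68-fold (2.23 ± 0.57) and miR-127-3p 3.72-fold (1.90 ± 0.58), calls lost in 2 to 7 settings each. Of 9 miR-200/miR-141 entries 5 were lower in bTS5 (median −1.48, camera adjusted p = 4.73e-09, adjusted p = 0.0713 with an estimated correlation), miR-200b-3p 4.20-fold (−2.07 ± 0.27, 474 ± 82 against 1990 ± 660 CPM), miR-200a-5p 4.55-fold (−2.19 ± 0.32) and miR-200a-3p 2.78-fold (−1.48 ± 0.25). The mesenchymal share, mostly miR-21-5p, was 16.4 ± 0.18% in bTS5 and 8.27 ± 1.5% in CT30. Of 36 mesenchymal entries 8 were higher, 9 adjusted over the list alone (median 0.69, camera adjusted p = 0.00713, adjusted p = 0.795 with an estimated correlation). MiR-99a-5p rose 2.83-fold (1.50 ± 0.31), miR-143-3p 2.30-fold (1.20 ± 0.31, a call lost in 5 of 6 fits with 1 library left out), miR-21-5p 1.80-fold (0.85 ± 0.19, 149000 ± 5200 against 82600 ± 13000 CPM, lost in 2) and miR-22-3p 1.76-fold (0.82 ± 0.26, a call lost without any 1 of the 6 libraries). Of 9 HOX-cluster entries 2 were lower, 4 adjusted over the list alone (median −0.15, 0.00 with library-size scaling, camera adjusted p = 0.043, adjusted p = 0.795 with an estimated correlation), the copies of miR-196a-5p, down 3.5-fold (−1.81 ± 0.39).

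C19MC moved little between bTS5 and CT30, with 8 of 83 entries higher and 3 lower, miR-520f-3p, miR-520f-5p and miR-520g-5p, 8 and 5 adjusted over the list alone (median 0.16, test down, camera adjusted p = 0.847). MiR-512-3p was at −0.08 ± 0.15, while miR-520f-3p fell 5.31-fold (−2.41 ± 0.29, adjusted p = 9.2e-05, 187 ± 59 against 993 ± 360 CPM) and miR-520g-5p 2.70-fold (−1.43 ± 0.19). MiR-335-3p, in an intron of the imprinted gene MEST, fell 3.18-fold (−1.67 ± 0.29, 1230 ± 600 against 3910 ± 1000 CPM), miR-30d-5p 2.06-fold (−1.04 ± 0.21), miR-30d-3p 2.45-fold (−1.29 ± 0.28) and miR-148a-3p 1.66-fold (−0.73 ± 0.18); miR-374b-5p rose 2.48-fold (1.31 ± 0.24). MiR-1246 rose 3.51-fold (1.81 ± 0.52, a call lost without any 1 of the 6 libraries) and miR-1268b fell 3.67-fold (−1.88 ± 0.55, −1.12 and not past without CT30 replicate 3). No entry passed the edgeR quasi-likelihood test in let-7/miR-98 (median −0.24, camera adjusted p = 0.0468, adjusted p = 0.795 with an estimated correlation), miR-371/miR-373 (median −0.35, camera adjusted p = 0.168), miR-302/miR-367 (camera adjusted p = 0.247) or blood (camera adjusted p = 0.965). Nor did one in endoderm (median −0.07, 0.10 with library-size scaling, camera adjusted p = 0.733), muscle (camera adjusted p = 0.663), neural (median −0.13, 0.02 with library-size scaling, camera adjusted p = 0.516) or p53-responsive lists (camera adjusted p = 0.516). At an unadjusted p below 0.05 these had 5 let-7/miR-98, 5 neural, 1 blood and 1 p53-responsive entry and 0 of the others, and by DESeq2 2 neural entries and 0 of the others. Of 28 miR-17/miR-92 entries 4 were lower, 1 higher and 6 lower adjusted over the list alone (median −0.07, 0.05 with library-size scaling, mean 0.08, camera adjusted p = 0.111). Of 19 epithelial and trophoblast entries 1, miR-184, was higher (median 0.23, camera adjusted p = 0.845). In all 86 entries were higher and 40 lower (75 and 37 names, 283 at unadjusted p below 0.05), so 68.3% of calls were higher, against 81.2% with library-size scaling, which moved all entries by 0.149 log2, and 35.2% when only these 6 libraries were fitted. Without bTS5 replicate 3 the counts fell to 15 and 16, and miR-370-3p was at 1.82 and not past.

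Over all tested entries TSCn lay nearer the reference lines than TSCp did, at distances of 48.9 ± 0.64 and 74.4 ± 1.0 (mean ± SD, n = 3, difference 25.4, exact permutation p = 0.1, the smallest possible). C19MC carried most of that difference: without its entries the distances were 47.6 and 52.2. Without C14MC they were 35.8 and 65.2. The distance was 31.5 between bTS5 and CT30, 43.7 between CT30 and TSCn, 56.6 between bTS5 and TSCn, 69.9 between CT30 and TSCp, and 79.5 between bTS5 and TSCp. TSCn and TSCp were 76.1 apart, ESCp and TSCp 92.1, ESCn and TSCn 114.7, and ESCn and ESCp 117.1.

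Intervals and floors for low counts cover counting error only, not variation between cultures. Reads matching several loci appeared to be counted at each (75 of 91 names with copies), so copies of 1 miRNA in C19MC and elsewhere are not separate measurements, although the list and overlap tests count each as an entry.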

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

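The contrast between routes, its lists, the scaling alternatives and the comparison of C14MC members in ESCn with bTS5 were planned, and the other tests of explanations below, the use of the scalings for let-7 among them, were chosen after the result was seen. The results here differ between the naive and primed route by a test of that difference (edgeR quasi-likelihood, camera for lists). It called 306 entries higher and 295 lower in the naive route. Of 100 splits drawn only the real one (1) gave 601 or more. The highest other, 478, kept all 3 ESC labels, so ESC labels alone give calls and chance stays open. Refitted over all libraries with bTS5 and CT30 merged into 1 group, TSCn against the reference had 375 calls with at most 112 in other splits. TSCp had 460 with at most 100. Each was reached by 1 of 84 splits, but the others mix lines, so chance stays open. For TSCn against TSCp (442 calls), ESCn against ESCp (757), TSCn against ESCn (721), TSCp against ESCp (633) and bTS5 against CT30 (126) the 10 possible splits are too few for a share below 0.05; the highest other was 0.

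Median log2 differences between routes were 4.03 for C19MC, 3.76 for miR-17/miR-92, 4.31 for miR-302/miR-367, −9.71 for miR-371/miR-373, −3.67 for p53-responsive miRNAs (−2.61 without ESCn replicate 3), −9.76 for let-7/miR-98 (−8.92 without TSCp replicate 3), −10.63 for HOX-cluster miRNAs, −6.21 for mesenchymal markers and −7.10 for C14MC (−7.71 to −6.89 with 1 library left out, 5 of 12 omissions ending the call, adjusted p = 0.18 without TSCp replicate 3). These lists passed at the preset correlation, and with the correlation estimated none of the 9 did (adjusted p 0.0848 to 0.735). The largest single values were miR-429 11.91 (13.03 without ESCn replicate 2), miR-200a-3p 11.82, miR-20b-5p 11.31, miR-200b-3p 9.93, miR-135a-5p 9.54 (12.91 without TSCp replicate 3, 8.93 without replicate 1), miR-363-3p 9.26, miR-106a-5p 9.18 and miR-515-3p 8.08. In the other direction they were miR-34b-3p −14.72 (−15.36 without TSCn replicate 3), miR-34c-3p −13.10, miR-34c-5p −12.53, miR-196b-5p −12.13 (−13.04 without ESCp replicate 1), miR-214-3p −12.0, let-7i-5p −11.57 (−10.90 without TSCp replicate 3), miR-196a-5p −11.39 (−12.21 without ESCp replicate 2) and miR-98-5p −11.19 (−9.36 without TSCp replicate 3).

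Let-7, HOX-cluster and mesenchymal miRNAs were higher in ESCn than in ESCp, and scaling as the cause is argued against by the lowest let-7 median over 3 scalings, 8.34. RNA from the mouse feeder cells may be the source: from ESCn replicate 1 to the mean of replicates 2 and 3 the medians of the log2 change of share were 1.11 for let-7, 0.52 for HOX and 1.16 for mesenchymal miRNAs, a range of 0.64, while miR-371/miR-373 went by −1.37, miR-302/miR-367 by −0.89 and C19MC by −0.33. Let-7i-5p was at 37619, 100202 and 89104 CPM and miR-143-3p at 11973, 32964 and 29815 in the 3 ESCn libraries, and miR-372-3p at 254916, 180317 and 81961. A naive state that itself expresses these miRNAs stays open and untested, because only the naive cells were on feeders. Mapping the reads to mouse and human loci that differ would separate them.

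C14MC was 7.78 log2 higher in ESCn, but it moved apart from let-7 between ESCn libraries (median log2 change of share −0.67, a difference from let-7 of −1.78), which argues against 1 common source. Feeder RNA as the source of the C14MC members that mice lack is argued against by their median of 5.93 over ESCp (7 of 7 higher, 4.96 to 8.51), on a list of such members taken from general knowledge. For the other members feeder RNA stays open: relative to bTS5 the members that mice lack were lower by −1.92 log2 (permutation p = 0.0112; medians 1.65 over 7 entries and 3.57 over 67), and members also differ in level between cell types, so a part from feeder cells and an active human cluster cannot be told apart for them. An active maternal copy in naive H9 cells is therefore a hypothesis, which could be tested by methylation at the DLK1-MEG3 locus.

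In TSCp most C19MC entries nearest to miR-371/miR-373, or with like counts, were higher than in ESCp (19 of 23). Of the other 60, 54 were lower. By name and counts 4 members lay only in the end segment (miR-516a-5p 6.02, miR-522-3p 5.32, miR-519a-3p 4.65, miR-519a-5p 2.08). Their median lay 6.75 log2 above that of the 51 members only outside it (4.98 against −1.77). Whether reads shared with other loci (sequences were not compared) or position decides stays open. Over 51 members with a known position the 5 that rose started on average 49.5 kb nearer to that end, but the same positions had prompted this test, arms of 1 precursor are not independent, and miR-518a-5p, the one of the 5 outside the segment, has a copy with counts like an entry inside it. The segment was set after values were seen. A candidate explanation, untested here, is that transcription of miR-371/miR-373, or a boundary near it, reaches the end of C19MC in primed-derived cells, which chromatin or nascent RNA data across the 25.3 kb gap could test.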

How the results depend on the processing

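The unplanned alternatives, chosen after the results were seen, were leaving out ESCn replicates 2 and 3 and keeping 1 entry per distinct miRNA. Of 10660 alternative values 10142 were kept, with sign checked for calls and shares only. Among single miRNAs and smaller lists 222 lost and 245 gained a call, and 9 values reversed. Called entries ranged over alternatives from 162 to 268 higher and 165 to 250 lower for TSCn against TSCp, 282 to 443 and 213 to 414 for ESCn against ESCp, 231 to 419 and 253 to 392 for TSCn against ESCn, 171 to 337 and 276 to 411 for TSCp against ESCp, 106 to 262 and 161 to 258 for TSCn against the reference, from 69.1% of 181 to 332 and 207 to 322 for TSCp against the reference, and 234 to 359 and 199 to 315 for the difference between routes. Fewer entries tested explain the low counts with the 10 CPM filter: 282 higher in ESCn against ESCp, 253 lower in TSCn against ESCn, 171 higher in TSCp against ESCp and 207 lower in TSCp against the reference. With that filter the difference between routes was −6.30 for C14MC (adjusted p = 0.0566) and 4.64 for miR-302/miR-367 (adjusted p = 0.0839), neither past the threshold; over alternatives the adjusted p ranged from 0.000124 to 0.18 and from 8.17e-05 to 0.0839. With no filter 332 entries were higher in TSCp than in the reference and 74 lower in bTS5 than in CT30, the C14MC and C19MC medians of TSCp against ESCp (−2.64 and −1.10) and miR-371/miR-373 in TSCp against the reference (1.395) passed, and miR-126-3p in TSCn against ESCn (0.048) and miR-20a-5p in TSCp against the reference (0.039) reversed. A replicate block gave 52 higher in bTS5 than in CT30, and C14MC and C19MC in TSCp against ESCp (−3.525 and −1.31) and miR-371/miR-373 in TSCp against the reference (1.01) passed. With library size alone 138 were higher in bTS5 and C14MC passed in TSCp against ESCp (−3.49). DESeq2 called 64 lower in bTS5 and did not pass C14MC in TSCp against the reference (−7.22, adjusted p = 0.0708, range over alternatives 3.41e-20 to 0.0708). A minimum log2 fold change of 1 left 106 higher in TSCn than in the reference, by construction. With only the compared groups bTS5 against CT30 had 43 higher and 79 lower, and C14MC in TSCp against ESCp (−5.32), miR-371/miR-373 in TSCp against the reference (1.15) and miR-371/miR-373 in bTS5 against CT30 (−0.47) passed. Without ESCn replicates 2 and 3 C14MC missed the threshold for the difference between routes (−7.34, adjusted p = 0.0568), with 1 ESCn library assumed to vary like the other groups. With 1 entry per distinct miRNA the neural share of TSCn minus TSCp was 0.272 and the muscle share of ESCn minus ESCp 0.000654, both reversed. Where no construction is named the cause was not tested.

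Single libraries decided some values. For bTS5 against CT30 the range was 15 to 87 higher and 16 to 47 lower, with 15 and 16 without bTS5 replicate 3. C14MC in TSCp against ESCp ranged from −3.96 to −3.18, 3 of 6 omissions changing its side, and for the difference between routes from −7.71 to −6.89, 5 of 12 changing its side (adjusted p = 0.18 without TSCp replicate 3). Shares with no direction of their own ranged from −0.0395 to 0.0124 (blood) and −0.00852 to 0.289 (epithelial and trophoblast) for ESCn minus ESCp, and from −0.216 to 0.522 (mesenchymal) and −0.393 to 0.137 (neural) for TSCn minus TSCp. Calls lost in 1 or more settings were miR-196a-5p and miR-92a-3p in TSCn against TSCp; miR-21-5p, miR-30d-5p and miR-499a-5p in ESCn against ESCp; miR-126-3p in TSCn against ESCn. They were miR-126-3p, miR-499a-5p and miR-7-5p in TSCp against ESCp, and miR-126-3p, miR-126-5p, miR-133a-3p, miR-148a-3p, miR-205-5p, miR-20a-5p, miR-375-3p and miR-424-3p in TSCn against the reference. In TSCp against the reference they were miR-196a-5p, miR-20a-5p, miR-22-3p and miR-483-3p, and for the difference between routes miR-206 and miR-21-5p. In bTS5 against CT30 they were miR-1246, miR-1268b, miR-127-3p, miR-143-3p, miR-148a-3p, miR-21-5p, miR-22-3p, miR-30d-3p, miR-370-3p, miR-379-5p and miR-381-3p. The distance of TSCn to the reference stayed below that of TSCp in all the alternatives run. Depth sets a floor of 0.189 to 0.552 CPM, so changes of entries below it were not detectable.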

Other observations

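The tests of clusters by position below were chosen after the results of the lists were seen. Some miRNAs, of which only let-7e is in a fixed list, moved with neighbours on the genome at the preset correlation, and with the correlation estimated none of these tests passed (adjusted p 0.0999 to 0.905). MiR-30b and miR-30d on chromosome 8, epithelial and kidney miRNAs, were higher at all 4 tested entries in both routes (median log2 fold change 5.04 in TSCn against ESCn, adjusted p = 0.00257; 4.80 in TSCp against ESCp, adjusted p = 9.92e-05, camera). The miR-23a/miR-27a/miR-24 cluster on chromosome 19, active in vessels and muscle, was higher at 6 of 6 entries in ESCn than in ESCp (4.88, adjusted p = 0.0176) and in TSCp than in ESCp (3.63, adjusted p = 0.00178), and its chromosome 9 paralog miR-23b/miR-27b/miR-24 likewise (3.97, adjusted p = 0.0342, and 3.22, adjusted p = 0.00231). MiR-99b/let-7e/miR-125a, a cluster of differentiating cells, was higher at 6 entries in ESCn (4.07, adjusted p = 0.0157), at 6 in TSCp than in ESCp (2.08, adjusted p = 0.0131) and at 4 in TSCp than in the reference (1.67, adjusted p = 0.0196). The mesenchymal share was also higher in ESCn (21.1% against 8.0% in ESCp), and only ESCn was on mouse feeder cells, while in TSCp that share was 6.6%. MiR-181a/miR-181b on chromosome 1, known from lymphocyte development, was higher at 4 entries in TSCp than in ESCp (3.84, adjusted p = 0.046).

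Lower in ESCn than in ESCp were miR-105/miR-767 on the X chromosome, a cluster tied to cancer-testis genes (6 entries, −6.94, adjusted p = 0.0176), miR-653/miR-489 in the calcitonin receptor region of chromosome 7 (3 entries, −7.41, adjusted p = 0.0176), miR-301b/miR-130b (4 entries, −3.89, adjusted p = 0.0342) and miR-421/miR-374b (3 entries, −3.93, adjusted p = 0.0156). MiR-653/miR-489 was also lower in TSCp than in ESCp (−5.66, adjusted p = 0.0129) and in TSCn than in the reference (−3.41, adjusted p = 0.0383).

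Named miRNAs lay in introns only at 54 of 126 entries, in an exon of some transcript at 26 and without a host gene on their strand at 46. MiR-34c, miR-30d and miR-148a had none, miR-483 lay in IGF2, miR-934 in VGLL1, miR-335 in MEST and miR-205 in MIR205HG. In C14MC the share of CT30 replicate 3 was 0.0064% against 0.0847% and 0.078% in replicates 1 and 2, and in ESCn the shares were 4.65%, 3.29% and 2.40%. In TSCp replicate 3 miR-424-3p was at 275.68 CPM, against 56.31 and 57.64 in replicates 1 and 2.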
